A study of Mus musculus with 2 samples.

How the data were processed

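Chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed in mouse E14 embryonic stem cells: 1 PHF19 ChIP library and 1 input library, grouped by the antibody given in the labels. The authors deposited aligned reads of both libraries as lines of chromosome, start, end and strand, aligned to mm8 with Bowtie per the submitters' processing notes (its version is not given in the sources used here). Every line was 42 bases long. Counts of reads were made here from these deposited lines. The authors also deposited 1 list of 3445 peaks, named as MACS output per the file headers, with a score per peak that is the authors' own and was used only to rank peaks within the list. Whether the input served as control in peak calling, the settings of the caller and the treatment of reads with several matches are not given in the sources used here. Libraries were amplified by PCR and size-selected on a gel, per the labels' protocols.

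Reads at the same chromosome, 5′ end and strand were kept once, which removed 8.38% of ChIP and 7.33% of input reads. Of the removed reads, 52.8% (ChIP) and 45.2% (input) lay in 10 bins of 10 kb. The plan was to move each library's 5′ ends inwards by 0.5 of its own fragment length, read from the lag between strands. The lag of the ChIP library was largest at 40 bp, close to the read length of 42, so it gave no fragment length. The input's lag of 109 bp over the autosomes was used for both, a shift of 54 bp, and this was chosen after the lags were seen. Inside peaks the lag was largest at 37 bp in the ChIP and 41 bp in the input. Reads in peaks therefore gave no fragment length in either library. Fold is the ChIP share of reads divided by the input share, each over the library's distinct reads. An input count of 0, found in 2 peaks, was replaced by a floor of 3 counts.

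Peaks were tested with an exact two-sided conditional binomial test and called at an adjusted p of 0.05 (Benjamini-Hochberg) and a fold of 2. Bins of 1 kb with at least 5 reads in both libraries together were tested one-sided with the same thresholds. Intervals are exact (Clopper-Pearson for shares and folds, Poisson for densities) at 95%. Peak positions were compared with 1000 random placements of the same widths on the same chromosomes. A peak counted as having raised input at 2 times the median input of its chromosome. On simulated counts with 200 changed regions, the peak test called 37.3%, 86.6% and 97.0% of peaks changed 2-, 4- and 8-fold among 3445, and the bin test 0%, 31.3% and 89.4% among 2462451 autosomal bins. In the data 3395 peaks were called, far more than the 200 changed there, so the adjusted threshold was stricter in the simulation. The fold threshold of 2 by itself also leaves out many peaks changed 2-fold. The simulated shares therefore do not give the rate of detection in these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

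Regions are named by a fixed rule: the 10 peaks with the highest authors' score, the 10 with the largest fold and at least 20 ChIP reads, the 5 widest, the 5 called bins outside peaks with the most ChIP reads, and the 5 windows of 1 Mb with the most peaks. A gene annotation of mm8 was not used here, so peaks were not assigned to genes. The planned analyses of peak position relative to genes and of promoters, with 10 gene lists of 288 members, were not run. The gene table at hand is of the GRCm38.p6 assembly and gave only names and chromosomes of genes. Alternatives covered duplicates, shift, scaling, thresholds, bin size, read minimum, peak set and placement; a setting without a read minimum still needs 1 read in a bin.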

Results

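The data describe chromatin recovered with an antibody against PHF19, a Polycomb-like protein that associates with the Polycomb repressive complex PRC2. The cells were mouse E14 embryonic stem cells, a line grown on gelatin and kept pluripotent with the cytokine LIF. DNA recovered with a rabbit polyclonal antibody against PHF19 (the PHF19 ChIP library) was set against input DNA sequenced without immunoprecipitation. Neither library was a control for the specificity of the antibody. Enrichment over input therefore shows what the antibody recovered, which need not be PHF19 alone. There was 1 library per group, so no value has a replicate error, and each test compared the reads of these 2 libraries, not conditions. The ChIP library held 23965625 aligned reads at 21957101 distinct positions, and the input 26433784 at 24496988. A bin of 1 kb held a median of 8 ChIP and 9 input reads. Intervals are 95% intervals for counting error only, since there was 1 library per group. They may be too narrow even for that, because amplified reads are not independent molecules. Intervals of densities per Mb also treat peaks and bins as independent, although peaks lay in groups, so they are too narrow. All coordinates are those of the mm8 build, and no position was assigned to a gene.

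The first comparison asked whether PHF19 ChIP reads were enriched over input at the 3445 peaks that the authors deposited. Reads in peaks made up 1.30% of the ChIP library (1.299 to 1.308, exact binomial interval, 286243 reads) and 0.366% of the input (0.364 to 0.368, 89664 reads), a ratio of 3.56 (3.54 to 3.59). The 3445 peaks covered 6200.6 kb, with a median width of 1425 bp. Of these, 3395 (98.5%) were called enriched by an exact two-sided conditional binomial test with Benjamini-Hochberg adjustment and a fold of at least 2. The median fold was 3.68, with quartiles of 2.93 and 4.70. Among the 50 peaks not called, 48 passed the adjusted test at a fold below 2 and 2 did not pass it. No peak had a fold at or below 1. At a fold of at least 4, 1400 peaks were called. The authors' peaks were called on these same ChIP reads, so enrichment at them is not independent evidence of binding.

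**Figure D1:**
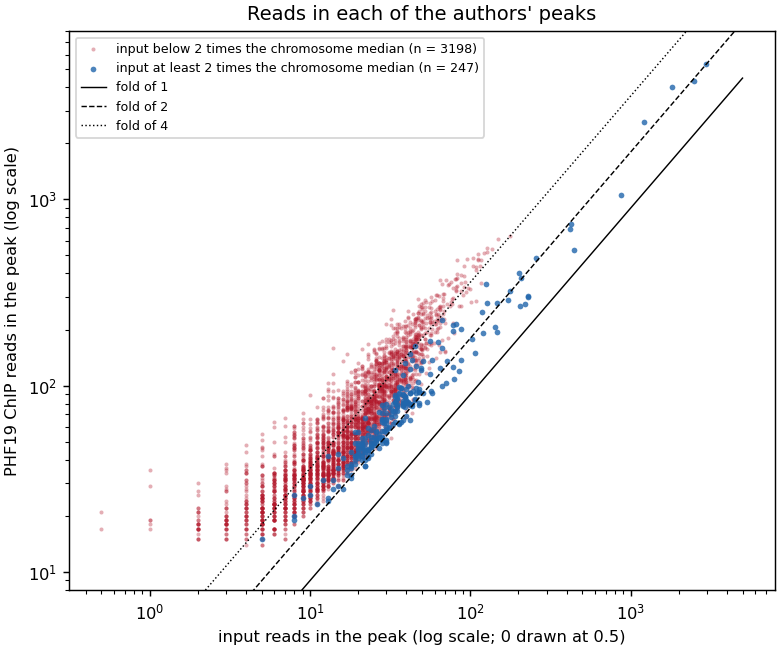
Reads of the PHF19 ChIP library against reads of the input in each of the 3445 authors' peaks, both on log scales, with lines for folds of 1, 2 and 4 after scaling to library size. Points are peaks, and the 247 peaks with at least 2 times the median input density of their chromosome are drawn in blue. All peaks lie above the line for a fold of 1.

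By the authors' score, the strongest peaks outside regions of raised input lay on chromosomes 9, 5, 17, 11 and 19. The peak at chromosome 9, 62938936 to 62949659, held 612 ChIP and 148 input reads, a fold of 4.61 (3.85 to 5.56; exact test, adjusted p = 1.38e-76). At chromosome 5, 38108973 to 38117972, the fold was 6.32 (4.99 to 8.08; 470 against 83 reads), and at chromosome 5, 33746342 to 33753632, it was 5.61 (4.50 to 7.07). The peak at chromosome 17, 85519075 to 85529540, had a fold of 5.22 (4.22 to 6.52). On chromosome 11, the peak at 96112613 to 96122392 had a fold of 4.78 (3.91 to 5.87), and the one at 84335008 to 84344335 had 4.41 (3.65 to 5.35). The peak at chromosome 19, 45281470 to 45290931, had a fold of 4.75 (3.86 to 5.90). These 7 peaks were 7291 to 10724 bp wide, and their input density was 0.922 to 1.38 times the median of their chromosome. Peaks with higher authors' scores were also wider and held more ChIP reads, so width is no separate measure of strength. The 861 highest-scoring peaks had medians of 2698 bp in width, 136 ChIP reads and a fold of 4.69. The 862 lowest-scoring ones had medians of 866.5 bp, 29 reads and 2.98.

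The 3 highest authors' scores belonged to much wider peaks in which the input was raised as well. The peak at chromosome 6, 47580016 to 47616764, held 5333 ChIP and 2942 input reads, a fold of 2.02 (1.93 to 2.12), at 8.90 times the median input density of the chromosome. The neighbouring peaks at chromosome 8, 126423049 to 126477780 and 126477841 to 126510903, had folds of 2.47 (2.34 to 2.61) and 2.42 (2.26 to 2.59), at 3.67 and 4.06 times the median. Another wide peak, at chromosome 6, 47666497 to 47696709, had a fold of 1.95 (1.85 to 2.04) and was not called. The remaining one of the 5 widest peaks, at chromosome 2, 38167818 to 38180085, had a fold of 4.01 (3.39 to 4.76) at 1.60 times the median. In all, 247 peaks had an input density of at least 2 times the median, held 14.0% of the ChIP reads in peaks, and included 44 of the 50 peaks not called.

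**Figure D2:**
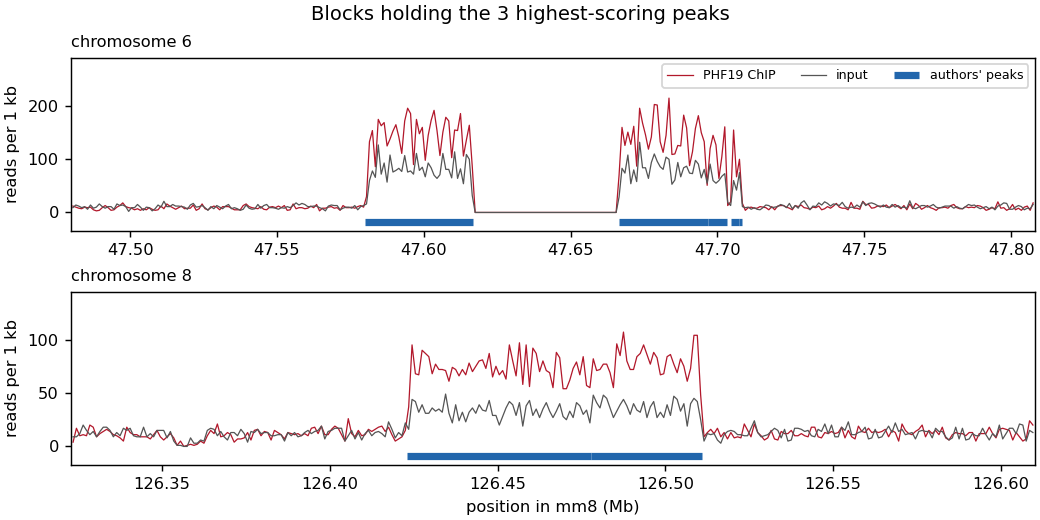
Reads per 1 kb bin of the PHF19 ChIP (red) and input (grey) libraries along the blocks on chromosomes 6 and 8 that hold the 3 highest-scoring peaks, by mm8 position, with the authors' peaks as blue bars. Both libraries rise together, with block folds of 1.99 on chromosome 6 and 2.45 on chromosome 8.

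The largest folds were found at narrow peaks with few input reads, where the order depended on the floor for low counts. Of the 10 named by fold, the one with the most reads lay at chromosome 17, 4582386 to 4583542, with 160 ChIP and 14 input reads and a fold of 12.8 (7.38 to 23.9; exact test, adjusted p = 8.32e-35). With duplicate reads kept, this fold was 20.2. At chromosome 6, 10135921 to 10136601, 38 reads against 3 gave a ratio of 14.1 (4.48 to 71.6), which became 26.1 with duplicates kept. At chromosome X, 98453374 to 98454305, 35 ChIP reads against 1 input read gave a ratio of 39.0 (6.56 to 1586), and at chromosome 14, 62202331 to 62203230, 29 reads against 1 gave 32.4 (5.36 to 1321). Ratios of 16.7, 15.1 and 14.5 at chromosomes 18, 1 and 4 rested on 2 input reads each. With every input count below 3 raised to 3, an alternative chosen after the values were seen, these 5 ratios lay between 9.67 and 13.0, and 6 of the 10 peaks stayed among the 10 largest. The peak at chromosome X, 99269227 to 99270266, had 91.9% of its ChIP reads on the plus strand.

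The second comparison searched the genome for enrichment without using the authors' peaks. Of 2531234 bins of 1 kb tested, 3982 (0.157%) were called higher in the ChIP by an exact one-sided conditional binomial test, and 7 were called higher in the input by the same test in the other direction. At an unadjusted p under 0.05, 96860 bins were higher in the ChIP. The called bins had a median fold of 4.71. Of these bins, 3805 (95.6%) touched an authors' peak. Called bins touched 2203 of the 3445 peaks (63.9%), against a mean of 0.324% and at most 0.668% in 1000 random placements of the peaks; both come from the same ChIP reads, so this overlap is not independent evidence. The 1242 peaks not touched were weaker, with a median of 35 ChIP reads and a median fold of 2.92 against 4.14 for the others. On simulated counts, the bin test called 31.3% of bins changed 4-fold and 89.4% of those changed 8-fold. Only 200 bins were changed there, fewer than the 3982 called here, so the adjusted threshold was stricter than in these data. The simulated shares therefore do not give the rate of detection at this depth.

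The 5 called bins outside peaks with the most ChIP reads lay in places of raised input. The bin from 165350001 on chromosome X held 174 ChIP and 93 input reads, a fold of 2.09 (1.61 to 2.71), at 18.6 times the median input. The bins from 4268001, 5000001 and 4027001 on chromosome 14 had folds of 2.30 (1.68 to 3.18), 2.46 (1.70 to 3.62) and 2.23 (1.47 to 3.45), at 7.63, 5.38 and 4.38 times the median. The bin from 15149001 on chromosome 5 had a fold of 2.70 (1.65 to 4.54) at 2.4 times the median. Most of the 177 called bins outside peaks were smaller, with medians of 23 ChIP and 3 input reads.

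The third comparison asked how the peaks lay along the chromosomes. They were strongly grouped. Another peak lay within 10 kb of 40.7% of the peaks, against 3.33% ± 0.412 (SD of 1000 random placements; two-sided permutation p = 0.002, the smallest these placements can give). The 4 windows of 1 Mb with the most peaks were on chromosomes 6, 15, 11 and 2. The window from 52 to 53 Mb on chromosome 6 held 35 peaks with a joint fold of 4.21 (3.92 to 4.53). The window from 102 to 103 Mb on chromosome 15 held 33 peaks at 4.24 (3.90 to 4.61), and that from 96 to 97 Mb on chromosome 11 held 32 at 3.68 (3.44 to 3.94). The window from 74 to 75 Mb on chromosome 2 held 26 peaks at 4.56 (4.17 to 4.99). The fifth window, from 37 to 38 Mb on chromosome 18, held 20 peaks at 3.18 (2.86 to 3.54), of which 8 were in the top-scoring part of the list. In 1000 random placements no window held more than 11 peaks.

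**Figure D3:**
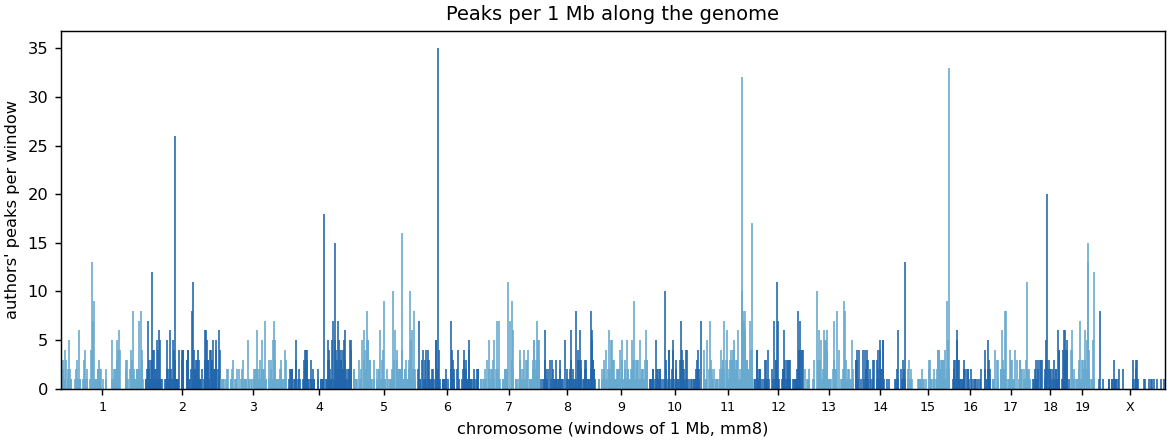
Number of authors' peaks in each window of 1 Mb along chromosomes 1 to 19 and X of mm8, with shades alternating by chromosome. The 4 tallest lines, 35, 33, 32 and 26 peaks, are on chromosomes 6, 15, 11 and 2.

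Within these windows the peaks ran together into stretches with gaps of at most 10 kb, which were picked out after their values were seen. The stretch at chromosome 11, 96067046 to 96190890, held 25 peaks over 124 kb at a fold of 3.89. Between its peaks the fold was still 1.94 (1.76 to 2.13). The stretch at chromosome 15, 102737903 to 102844382, held 24 peaks at 4.40, with 2.10 (1.90 to 2.33) between them. At chromosome 6, 52119432 to 52204698, 23 peaks had a fold of 4.47, with 1.90 (1.67 to 2.17) between them. On chromosome 2, stretches at 74456682 to 74513529 and 74524042 to 74564487 held 16 and 10 peaks at folds of 4.98 and 3.87. Outside the 5 windows, a stretch of 14 peaks at chromosome 4, 88227888 to 88278499, had a lower fold of 2.44 where the input was 2.22 times the chromosome median, and 12 of them were called. Of all 2502 stretches, 2044 held a single peak and 55 held at least 5.

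**Figure D4:**
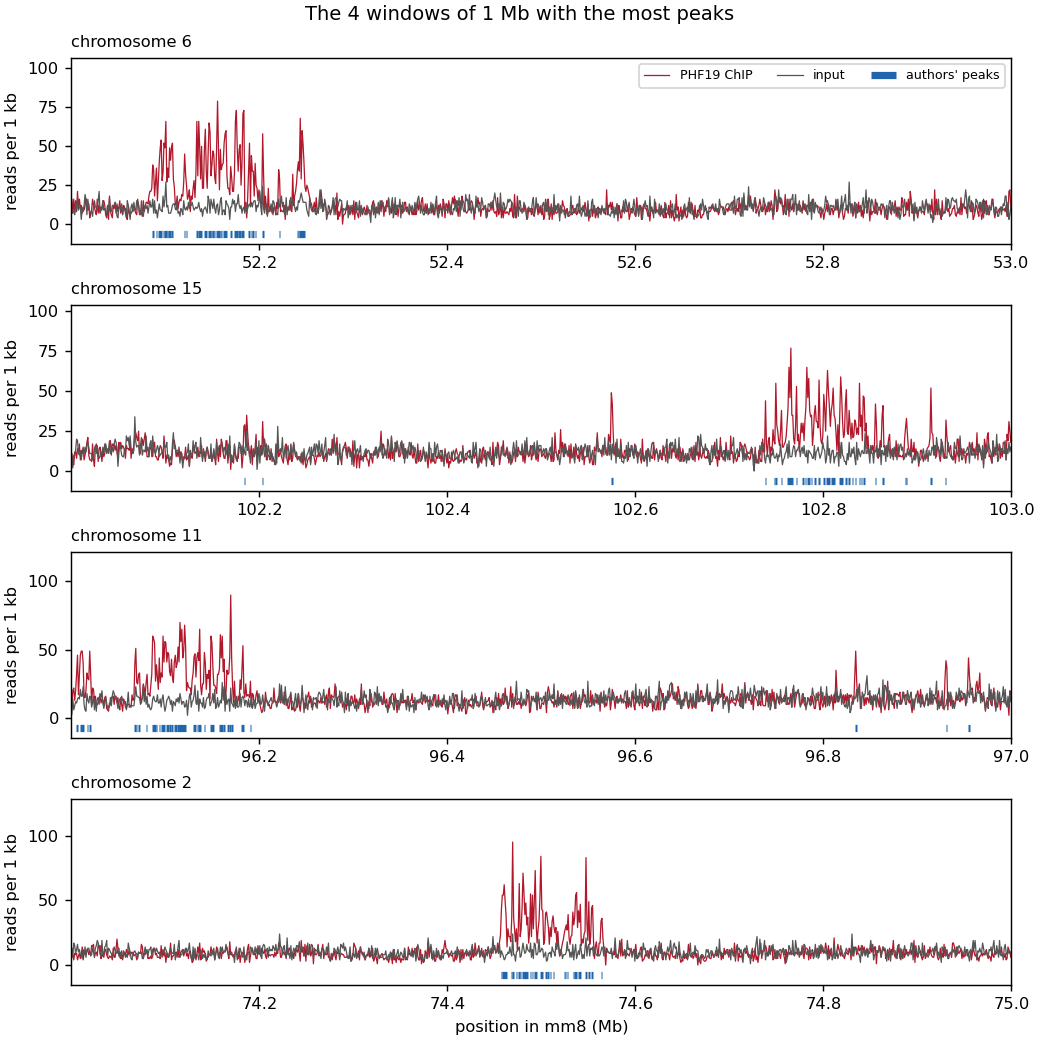
Reads per 1 kb bin of the PHF19 ChIP (red) and input (grey) libraries along the 4 windows of 1 Mb with the most peaks, by mm8 position, with the authors' peaks as blue bars. ChIP reads rise in blocks of neighbouring peaks while the input stays level.

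Enrichment fell off with distance from the peaks. Bins touching no peak had a fold of 1.39 (1.38 to 1.41) within 2 kb of one, 1.13 (1.12 to 1.14) at 2 to 5 kb and 1.06 (1.05 to 1.07) at 5 to 10 kb. Beyond 100 kb the fold was 0.981 (0.981 to 0.982).

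**Figure D5:**
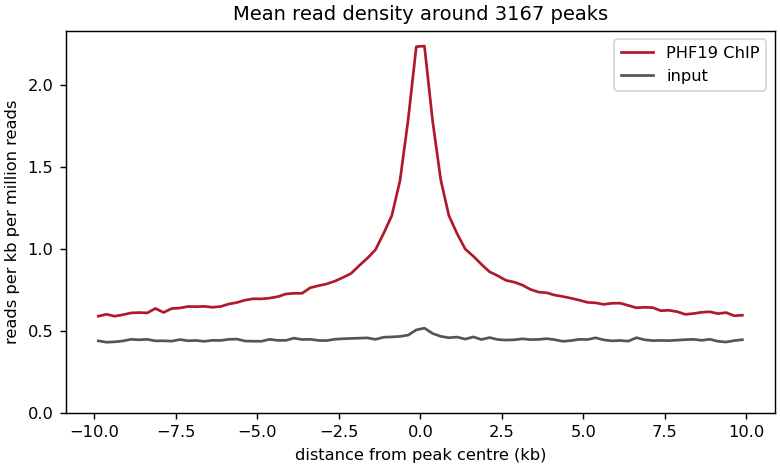
Mean read density of the PHF19 ChIP and input libraries, scaled to library size, around the centres of 3167 of the 3445 authors' peaks. Steps were 250 bp within 10 kb of the centre, and the remaining peaks were not drawn. The fold reached 4.42 beside the centre; neighbouring peaks were left in.

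Chromosome X carried fewer and narrower peaks than the autosomes, a comparison chosen after the values were seen. It held 51 peaks, or 0.308 per Mb (0.229 to 0.405, exact Poisson interval), while the 19 autosomes ranged from 0.835 on chromosome 16 to 2.38 on chromosome 11. All 51 were called enriched, with a median fold of 5.58 and a median width of 832 bp, against 3.67 and 1440 bp on the autosomes. The input held 5.35 reads per covered kb on X and 9.78 on the autosomes. Mitochondrial DNA, which carries no histones, was lower in the ChIP than in the input, with a fold of 0.606 (0.586 to 0.626). It held 324 ChIP and 597 input reads per covered kb. At such density, keeping 1 read per position and strand limits the counts, more so in the denser library. This fold and its interval are therefore only approximate.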

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

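The tests chosen only after the result was seen are those of raised input against copy number equal to the rest of the genome or equal in both libraries, the tests of each block on its own, the split of strand-skewed peaks by input reads, and the repeated thinning draws; thinning itself was chosen after the pattern on X was seen, with its bounds written before its result.

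Strand balance was not part of the comparisons. Plus-strand reads were in excess in both libraries, at 54.7% of ChIP and 53.8% of input reads, and the ChIP share was above the input by more than counting error on all 19 autosomes, by 0.483 to 1.18 percentage points. Wider gaps included those on Y_random and X. On Y_random, 82.84% of ChIP reads were on the plus strand, against 78.65% of input reads. On chromosome X the shares were 63.06% and 60.68%. These gaps were 4.19 and 2.38 percentage points.

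The 3 highest-scoring peaks lay in blocks where the input was at least 3.818 times the chromosome median; the blocks were put together from peaks of raised input, so this value does not test the usual copy number, which cannot be told apart from other states here. Equal extra copies in both libraries as the whole cause are argued against by folds of at least 1.986. Extra copies in different number would keep the ChIP share constant along both blocks, which was predicted before the result was seen and failed, with a chi-square of 2.398 per degree of freedom on chromosome 6. Taken alone, a split made after that failure, the block on chromosome 8 gave 0.917. Different copy number may therefore account for that block and stays open there. The block on chromosome 6 held more reads, 10762 ChIP and 6047 input, against 6624 and 3017 on chromosome 8. With more reads per bin, smaller departures from a constant share raise the value. The failed prediction therefore does not exclude different copy number on chromosome 6. For the 20 widest other peaks the chi-square per degree of freedom ranged from 0.435 to 4.62 (median 1.54). Of these, 4 were at or below chromosome 8 and 5 at or above chromosome 6. Those peaks were only 7.37 to 12.3 kb wide, against 72 and 85 bins of 1 kb in the blocks on chromosomes 6 and 8. The value spreads more with fewer bins and can change with read depth. This comparison therefore cannot show whether the blocks resemble ordinary wide peaks. No biological explanation was tested, as the design has no second cell population.

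In 37 peaks the ChIP strands were out of balance, 35 of them towards plus, by an exact binomial test against the plus share over all peaks at an adjusted p of 0.05. Placement of reads with several matches on the plus strand predicted over 65% plus-strand input reads in these peaks, and at most 55% otherwise. The pooled share was 61.21%, between both bounds, and was set by 6 peaks that held 3004 of the 3369 input reads at 58.7% plus, so this explanation and others cannot be told apart for the 37 peaks together. In the 31 with 50 or fewer input reads the share was 81.64% (77.3 to 85.5), so placement of such reads is a candidate explanation for those. In the 3408 peaks that did not pass the strand test it was 50.3%. The strand test used 1 plus share for all chromosomes. Of the 37 peaks, 7 lay on Y or Y_random, where 71.5% and 82.8% of all ChIP reads were on the plus strand. For those 7 the test did not separate a skew of the peak from that of its chromosome.

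Called bins were sparser on chromosome X, at 0.308 per Mb, with a median fold of 6.69 against 4.69 on the autosomes. After autosomal reads were thinned to the coverage of X, the median fold on X, 6.945, lay within the autosomal range of 5.99 to 7.24, so lower coverage may account for the fold. The density on X was then 0.2416 per Mb. In the first thinning the upper bound for X, 0.329, lay below the lowest autosome, 0.362, which met the bound written in advance against coverage; of the 20 thinnings drawn after that, the first included, 8 met it, though X was lowest in 20. Coverage as the whole cause predicted a density on X within the range of the thinned autosomes, which failed in all 20 draws. The median of the autosomal means was 0.604 per Mb. In the draws that did not meet the bound against coverage, the interval of X reached the lowest autosome. Those draws met neither bound, so coverage as the whole cause cannot be told apart there from other causes. The Poisson interval treats called bins as independent, although peaks lay in groups, so it is too narrow. A wider interval could only lower the number of draws that met the bound. The 8 draws that met it therefore do not decide against coverage as the whole cause.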

How the results depend on the processing

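Removal of doubted peaks, a floor of 3 for low input counts and bins higher in the input were tests chosen only after the result was seen. Thinning was also added later, with its bounds written before its result; the other alternatives were set before the data were examined. Among alternatives for counts and shares, 14 stayed within 1.5 times (counts) or the counting interval (shares) and 16 moved beyond it. Clustering passed its permutation test under all 4 of its alternatives, at p = 0.002; within 50 kb the share was 50.3%, against 13.7% at random. For named regions, 86 kept their direction and side of the threshold, or a count of peaks within 1.5 times, and 5 moved, none reversing. Those 5 were the windows' peak counts in the top-scoring part of the list. The share of ChIP reads in peaks, 1.30%, was 1.26% with duplicates, 1.31% unshifted, 0.990% in the top-scoring part of the list, 1.54% with peaks widened by 500 bp and 1.12% without peaks of raised input or skewed strands. The input share, 0.366%, became 0.352%, 0.258%, 0.502% and 0.279% with duplicates, top-scoring, widened and without doubted peaks. Enriched peaks numbered 1400 at a fold of 4. Of 3982 called bins, 2791 were called at a fold of 4. With 500 bp bins 2881 were called, over 1440.5 kb in place of 3982 kb, and with 5 kb bins 2311, over 11555 kb. Called bins numbered 1553 with autosomes thinned to the coverage of X (mean of 20 draws) and 7 when called higher in the input. The share of peaks touched was 54.0% when bins had to cover 50% of the peak, 48.7% at a fold of 4 and 67.2% with duplicates. The input lag fell from 109 to 40 bp with duplicates. Fewer reads or peaks, or a stricter bound, account by construction for the falls under thinning, peak removal, fold 4 and the required cover of 50%. Widened peaks can only gain reads, so the higher shares with widening also follow by construction. For the rest the cause was not tested. No paired analysis was possible because each group had 1 library. Planned analyses by gene were not run. In simulated counts with 200 changed bins, 0% of bins changed 2-fold were called. The adjusted threshold was stricter there than in these data, so this share does not measure the limit set by depth.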

Other observations

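The test here was chosen only after the result was seen. The 4 windows of 1 Mb with the most peaks lay on chromosomes 2, 6, 11 and 15, which are the chromosomes that carry the 39 Hox genes, regulators of body-axis patterning, in the GRCm38.p6 gene table. The chance that 4 windows drawn at random fall on these chromosomes, one on each, is 0.0001635, but the Hox chromosomes were looked up because the windows had been seen, so this value is no evidence for a link. The same windows led in the top-scoring part of the list, with 21, 20, 20 and 17 peaks on chromosomes 6, 11, 15 and 2. That the windows hold the Hox clusters is an untested hypothesis: it and other gene content cannot be told apart, because chromosomes and not positions were compared and mm8 gene positions were not used here.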
